A study of Mus musculus with 6 samples.

How the data were processed

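Total RNA from 6 mouse primary pancreatic cancer cell lines was hybridised to Affymetrix whole-transcript arrays with biotinylated cDNA, 1 array per line, per the labels. The labels give the genotype of each line, 3 as Hdac2wt and 3 as Hdac2ko, and no batch, passage, sex or pairing. Lines were numbered within each genotype in the order of their records, and a number names a line without pairing it with a line of the other genotype. The replicates are separate cell lines, the labels state nothing further about how they were cultured, and each p-value rests on 1 array per line.

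The deposited values are log2 signals, 1 per probe set and array, made by the authors with Affymetrix Expression Console and RMA (robust multi-array average), per the submitters' processing notes. As the method is defined, RMA corrects the background, applies quantile normalization between arrays and summarises the probes of a probe set by median polish, a procedure that compresses differences of dim probe sets. Software versions, the array library files and the genome build are not given in the sources used here. The values ran from 1.72 to 14.11 over the 6 arrays, and they were used as deposited. Array medians ran from 7.305 to 7.45 for lines labelled Hdac2wt and from 7.18 to 7.21 for lines labelled Hdac2ko, without overlap. No detection p-values were used here, so the background level of a probe set is unknown, and the number of arrays limits the precision.

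The deposited values covered 35556 probe sets. The platform annotation gave a single gene symbol for 21789, several for 1621 and none for 12146. Probe sets with 1 symbol were renamed through their Entrez identifiers with a RefSeq gene table of the GRCm38.p6 assembly, which matched 21698, and 91 kept the symbol of the platform. That table served for names alone, and no coordinates are given. For the 999 genes with several probe sets, the probe set with the highest mean over the 6 arrays was used. No filter on dim probe sets was applied, and 19938 genes were tested.

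Differential expression between lines labelled Hdac2ko and lines labelled Hdac2wt was tested on the log2 values with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of variance on mean level), with genotype as the sole term. P-values were adjusted over all genes tested by the Benjamini-Hochberg method with a threshold of 0.05 and no fold limit. All differences are given as Hdac2ko minus Hdac2wt, with standard errors and 95% intervals from the moderated fit. The Hdac2 level was also compared by an exact two-sided permutation test over 20 assignments, which cannot give a p below 0.1 with 3 lines against 3. Tables were read with data.table (version 1.17.8), and plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

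A set of 26 gene lists with 935 entries was fixed before the data were examined, and 867 entries were measured by a probe set with 1 gene. Lists were tested with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with the correlation estimated for each list and with fry. The adjusted p over all genes and the adjusted p over the list alone were both computed for each member. Genes are named by a rule fixed at the same time: Hdac2, the 12 genes with the largest positive and the 12 with the largest negative difference among those past the threshold (predicted loci and olfactory, small RNA and receptor segment genes left out), up to 4 members of each list that passed with the largest differences or otherwise the 2 with the smallest p, a fixed set of pathway genes, and Xist with the Y-linked genes. Kras, Trp53 and Ddx3y belonged to that set and were not measured by a probe set with 1 gene. Genes named beyond this rule (Vim, Kdr, Tek, Tie1, Ror1, H2-Eb1, H2-DMa, Epcam, Cdh1, Cpa1, Prss2 and members of the added lists) were chosen after their values were seen. A further 11 lists of markers of other cell types were written after the first comparison was seen and before their own values were looked at. They covered macrophages and dendritic cells, endothelial cells and fibroblasts with members held out of the first lists, T and NK cells, B and plasma cells, erythroid cells, mast cells, Schwann cells, pericytes with vascular smooth muscle, adipocytes and mesothelial cells.

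The alternatives planned before the data were examined were filters on probe sets below the 25th percentile or the median of mean signal, centring of each array on its median, repeated quantile normalization, cyclic loess, the mean of the probe sets of a gene, eBayes without a trend or with robust estimation, array weights, a threshold of 0.1, a fold limit of 2, the other list tests, and the omission of each line in turn. Alternatives added later were the mean of the immune and endothelial list as a covariate, and the omission of list members that mark other cell types. The procedure was tested on simulated values for the same comparison of 19938 genes, with 50 genes changed at each of 4 sizes. It recovered 32% of genes changed by 1 on the log2 scale, 78% at 2, 86% at 3 and 90% at 4, with 5 false calls, and it made 0 calls where no gene was changed. Each gene was drawn independently with normal noise. The simulation therefore does not show how many false calls variation shared between genes, or a difference of cell content, would give.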

Results

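Gene expression was measured in 6 primary cell lines from mouse pancreatic ductal adenocarcinomas driven by mutant Kras, 3 labelled Hdac2wt and 3 labelled Hdac2ko. Hdac2 encodes a class I histone deacetylase that works in co-repressor complexes, and the series asks what its status does in this tumour. Each line was measured on 1 array, and signals are log2 RMA values as the authors deposited them. Over the 19938 genes tested, the median signal was from 8.01 to 8.12 in lines labelled Hdac2wt. It was from 7.83 to 7.95 in lines labelled Hdac2ko, so the genotypes did not overlap in it.

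The signal of Hdac2 was not lower in the lines labelled Hdac2ko. The Hdac2 probe set read 10.83, 10.19 and 10.01 in the lines labelled Hdac2wt and 10.23, 10.63 and 10.80 in the lines labelled Hdac2ko, on the log2 scale. The means were 10.35 ± 0.43 and 10.55 ± 0.29 (SD, n = 3 each). The difference was 0.21 with an interval from -0.45 to 0.87 (limma adjusted p = 0.700, exact two-sided permutation p = 0.500 where 0.1 is the smallest possible). Which exons the probe set reads and which part of the gene was deleted are not given in the sources used here. Genotypes are therefore given as labelled throughout, and every direction below depends on those labels. The related deacetylase Hdac1 differed by 0.42 (SE 0.14, adjusted p = 0.248), Hdac8 by 0.52 (SE 0.27, adjusted p = 0.403) and Hdac3 by -0.01 (SE 0.18, adjusted p = 0.983), a sign that turned to 0.17 with each array centred on its median. Of 38 measured members of the HDAC co-repressor complexes, 0 passed the threshold over all genes and 0 when adjusted over the list alone (limma), and 4 were higher and 0 lower at an unadjusted p under 0.05. The member with the smallest p was Brms1, at 0.60 (adjusted p = 0.190), and the median of the list was 0.18 (camera adjusted p = 0.164, from 0.0261 without Hdac2wt line 1 to 0.790 over the alternatives). That median was 0.071 without Hdac2wt line 3, 0.36 with centring and 0.044 with cyclic loess.

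Transcripts of macrophages, endothelial cells and connective tissue were prominent among the differences between the genotypes, and those that passed the threshold were lower in the lines labelled Hdac2ko. In all, 418 genes passed the threshold, 385 lower and 33 higher in those lines (limma, adjusted over all genes). In each of the 418 genes the 3 values of one genotype lay outside the range of the other. Their selection on the same values makes that nearly certain, so it adds no evidence. Over all genes tested, 4457 or 22.4% had such separate groups, against 10% by chance for a single gene. Genes vary together across the lines, so the 10% gives no test of this share. At least a 2-fold difference was reached by 391 genes, 369 lower and 22 higher. At an unadjusted p under 0.05 there were 2974 genes, 1708 of them higher. Among the 172 measured genes of the lists of other cell types, 60 fell and 0 rose.

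The median difference of all genes was 0.12 in the deposited values, 0.29 with each array centred on its median, 0.10 with quantile normalization repeated and 0.00088 with cyclic loess. Centring gave 345 genes lower and 103 higher, so that 77.0% of calls were lower in place of 92.1%. The count depended on single lines, with 232 genes without Hdac2wt line 1, 238 without Hdac2ko line 1 and 192 without Hdac2ko line 2. Lower genes numbered 229, 214 and 190 in these 3 fits. Higher genes numbered 3 without Hdac2wt line 1, 8 without Hdac2wt line 2, 13 without Hdac2wt line 3 and 2 without Hdac2ko line 2. Of the 418 genes, 210, 317 and 276 kept their call without Hdac2wt lines 1, 2 and 3, and 205, 179 and 270 without Hdac2ko lines 1, 2 and 3.

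**Figure D1:**
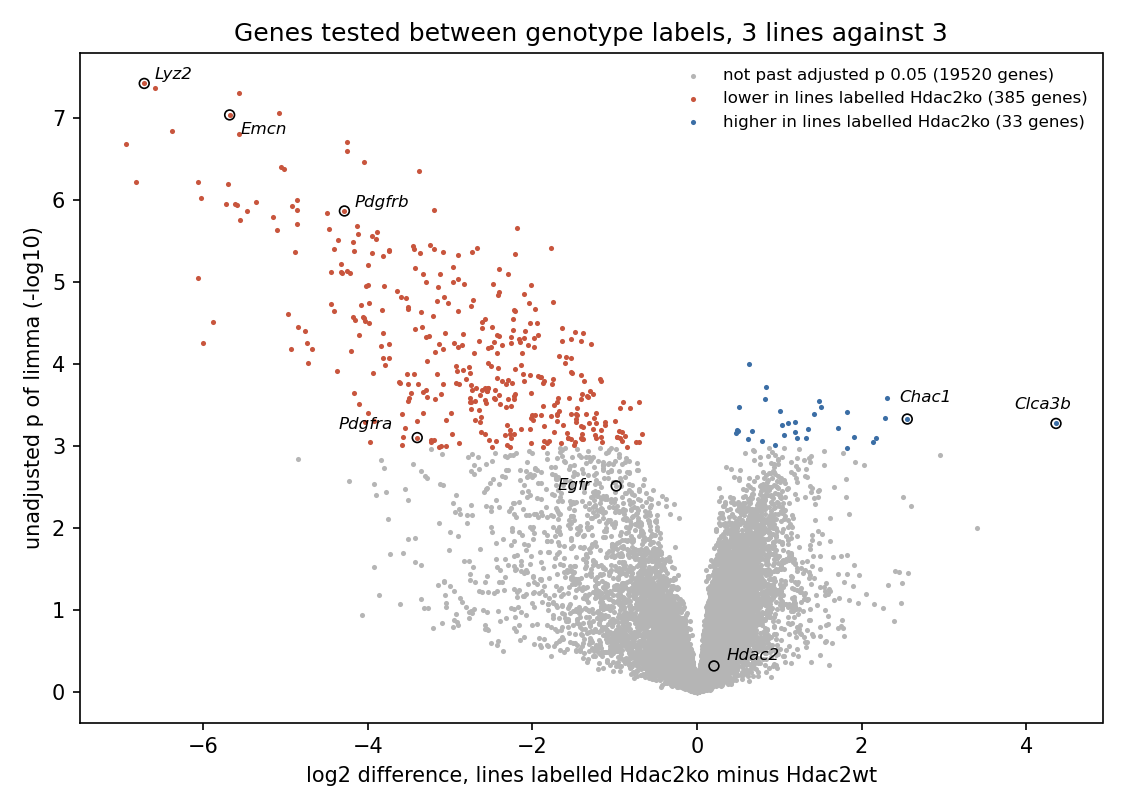
Difference between the genotypes on the log2 scale (horizontal) against the unadjusted p of limma on a -log10 scale (vertical), 1 point per gene for 19938 genes. The 385 genes past the threshold on the left reach a difference of -6.94, and the 33 on the right reach 4.36.

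The PDGF receptors, which bind platelet-derived growth factors and mark mesenchymal cells, were among the genes that fell. Pdgfrb read 11.32 ± 0.40 in lines labelled Hdac2wt and 7.03 ± 0.14 in lines labelled Hdac2ko (SD, n = 3 each), and fell by 4.29 (SE 0.25, limma adjusted p = 0.000975). Pdgfra read 10.44 ± 1.07 and 7.04 ± 0.55, and fell by 3.40 (SE 0.57, adjusted p = 0.0419). The call of Pdgfra ended without 1 line in each case but that of Hdac2wt line 2 (adjusted p = 0.0141), with adjusted p from 0.0576 to 0.164, and with repeated quantile normalization (adjusted p = 0.0521), no trend (adjusted p = 0.0525) or array weights (adjusted p = 0.0582). The epidermal growth factor receptor Egfr was at 10.71 ± 0.25 and 9.73 ± 0.23, a difference of -0.98 (SE 0.21) that did not pass over all genes (adjusted p = 0.0943). Adjusted over the list alone, that of 53 receptor tyrosine kinases, the limma p-values of Pdgfrb, Pdgfra and Egfr were 7.26e-05, 0.00524 and 0.0148, and adjusted over these 3 genes they were 4.11e-06, 0.00119 and 0.00307. Published work on this model discusses these receptors and may have chosen them on these samples, so neither smaller family is independent evidence. The fixed lists of immune and endothelial markers and of fibroblast markers, the second of which includes Pdgfra, shifted the same way, with medians of -2.37 and -2.42.

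**Figure D2:**
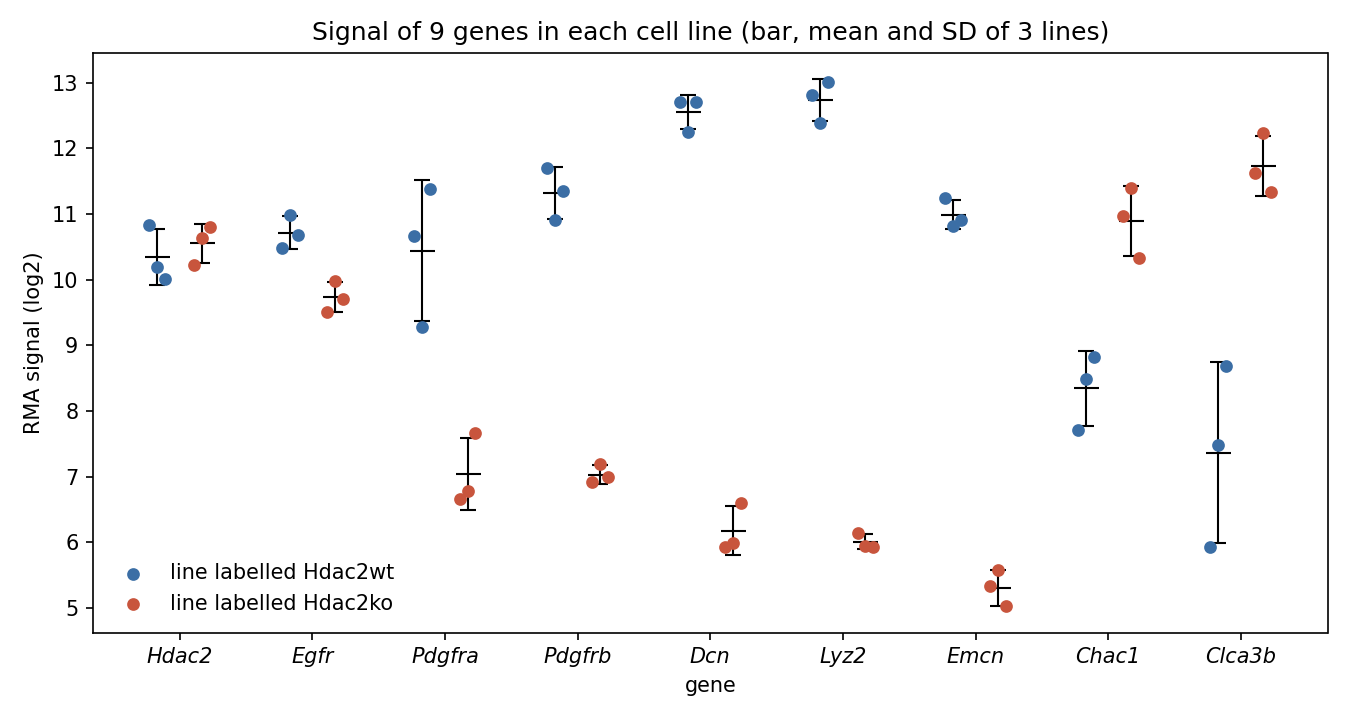
Log2 RMA signal (vertical) of 9 genes (horizontal) in each of the 6 lines, with points for single lines and bars for the mean and SD of the 3 lines of a genotype. Hdac2 overlaps between the genotypes, Lyz2 lies near 12.73 and 6.01, and Clca3b lies near 7.37 and 11.73 in lines labelled Hdac2wt and Hdac2ko.

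The 12 genes with the lowest differences fell by 5.70 to 6.94, and none of them lost its call when a line was left out. They held the macrophage lysozyme gene Lyz2, which was at 12.73 ± 0.32 in lines labelled Hdac2wt and 6.01 ± 0.12 in lines labelled Hdac2ko (limma adjusted p = 0.000337), and Ms4a6c, which fell by 6.94 (adjusted p = 0.000462). Srgn, the proteoglycan core protein of haematopoietic granules, fell by 6.82 (adjusted p = 0.000752). The matrix genes Postn and Dcn fell by 6.58 and 6.38 (adjusted p = 0.000337 and 0.000453), and the antigen presentation genes H2-Aa and Cd74 by 6.06 and 5.88 (adjusted p = 0.00240 and 0.00516). The others were Serpina3n, Ms4a6d, Wfdc17, Sparcl1 and the complement inhibitor gene Serping1. Lyz2, Serpina3n, Ms4a6c and Ms4a6d have near-identical relatives whose transcripts probes could share, so their single values are uncertain. The means of the 12 genes in lines labelled Hdac2ko, from 4.30 to 6.50, were not shown to lie above background, so these are differences of the deposited signals and do not give ratios of transcript amounts.

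The 12 highest genes rose by 1.48 to 4.36, and each lost its call in 4 to 6 of the 6 fits without 1 line. Clca3b, of a chloride channel regulator family with near-identical members and so uncertain, rose from 7.37 ± 1.38 to 11.73 ± 0.46 (SD, n = 3 each, limma adjusted p = 0.0318), with adjusted p from 0.0177 to 0.133 without 1 line. Chac1, an enzyme that degrades glutathione, rose by 2.56 (SE 0.39, adjusted p = 0.0296) and the monoamine oxidase gene Maoa by 2.31 (SE 0.32, adjusted p = 0.0198). Slc6a15, an amino acid transporter, rose by 2.18 and the chromatin remodeller Smarca1 by 2.13, with adjusted p of 0.0420 and 0.0447. Morn4, Dnph1, Lonrf3, Wasf1, Otub2, Ptpn22 and Steap1 rose by 2.28, 1.91, 1.83, 1.82, 1.71, 1.51 and 1.48. Lonrf3 stood at the threshold (adjusted p = 0.0499) and lost its call in all 6 of those fits. With all 6 lines, cyclic loess ended the calls of Slc6a15, Smarca1, Dnph1 and Lonrf3 (adjusted p = 0.0681, 0.0525, 0.0603 and 0.0627). The calls of Slc6a15, Smarca1 and Lonrf3 also ended without a trend (adjusted p = 0.0559, 0.0542 and 0.0551), those of Smarca1 and Lonrf3 with array weights (adjusted p = 0.0508 and 0.0565), that of Slc6a15 with repeated quantile normalization (adjusted p = 0.0601) and that of Lonrf3 with robust estimation (adjusted p = 0.0534).

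Markers of immune and endothelial cells, of fibroblasts and of mesenchymal cells fell together. Of 34 measured immune and endothelial genes, 19 fell and 0 rose over all genes, and 24 fell and 1 rose when adjusted over the list alone. Besides Lyz2 they held Emcn, an endothelial sialomucin, which fell by 5.68 (limma adjusted p = 0.000369), and the complement genes C1qb and C1qc, which fell by 5.59 and 5.10. Of 28 fibroblast and smooth muscle genes, 14 fell and 0 rose, with 19 lower when adjusted over the list alone. They included the collagen-binding proteoglycan genes Dcn and Lum, which fell by 6.38 and 5.57, and Mfap5 and Dpt, which fell by 4.88 and 4.11. Dpt lost its call without 1 line in 4 cases, with adjusted p up to 0.112. Of 39 mesenchymal genes, 15 fell and 0 rose, with 21 lower and 1 higher when adjusted over the list alone. Postn, the proteoglycan gene Bgn, the collagen cross-linking enzyme gene Lox and the cadherin gene Cdh11 fell by 6.58, 5.57, 5.47 and 4.44. Vim, the intermediate filament of mesenchymal cells, was at 13.38 and 13.37 in the 2 genotypes, a difference of -0.01 (SE 0.13, adjusted p = 0.964). The medians of the 3 lists were -2.37, -2.42 and -2.48 (camera adjusted p = 6.01e-38, 3.96e-27 and 6.22e-25). With an estimated correlation the calls were lost, at adjusted p = 0.0690, 0.0690 and 0.104. Without Hdac2ko line 1 the median of the mesenchymal list was -1.53.

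**Figure D3:**
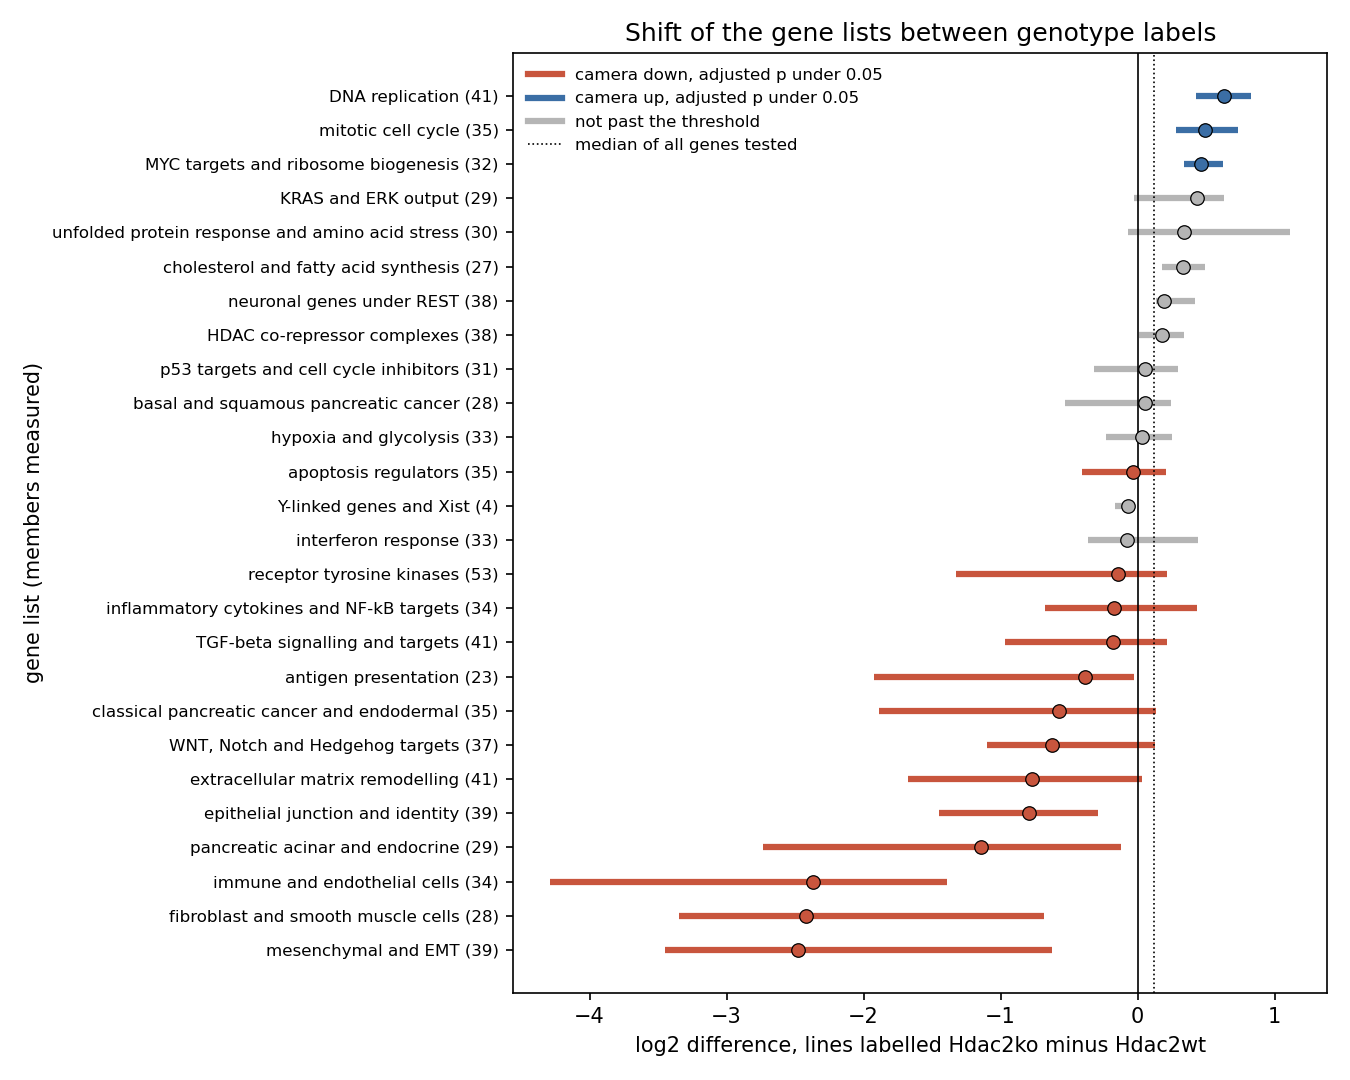
Median (point) and quartiles (bar) of the log2 difference between the genotypes for the measured members of 26 gene lists, coloured by the camera call at the preset correlation. The medians run from -2.48 for mesenchymal genes to 0.63 for DNA replication, and the dotted line marks the median of all genes at 0.12.

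Some receptor, matrix and presentation genes fell as well, while most members of these lists did not pass. Of 53 receptor tyrosine kinases, 8 fell and 0 rose, with 12 lower and 1 higher when adjusted over the list alone. Besides the PDGF receptors these were Csf1r, the receptor of macrophage growth factor, at -4.32, the ephrin receptor gene Epha3 at -3.05 (adjusted p up to 0.130 without 1 line), the endothelial receptor genes Kdr, Tek and Tie1, and Ror1. The median of the list was -0.14, turning to 0.03 with each array centred on its median (camera adjusted p = 1.82e-06, adjusted p = 0.0690 with an estimated correlation). It was -0.22 without Hdac2wt line 2, -0.069 without Hdac2wt line 3 and -0.079 without Hdac2ko line 2. Without the 6 members shared with the lists of other cell types, 3 of 47 fell and the median was 0.06, opposite in sign to the test. Of 41 matrix remodelling genes, 6 fell, and 11 when adjusted over the list alone, with a median of -0.77 (camera adjusted p = 1.42e-10, adjusted p = 0.161 with an estimated correlation). Col12a1, Mmp9, Lama3 and Adam12 fell by 4.42, 3.33, 2.31 and 2.26, and the last 3 lost their call without at least 1 line, with adjusted p up to 0.0966, 0.113 and 0.0503. Of 23 antigen presentation genes, 6 fell, and 7 when adjusted over the list alone, with a median of -0.38 (camera adjusted p = 1.08e-08, adjusted p = 0.161 with an estimated correlation). That median was -0.22 without Hdac2wt line 3 or without Hdac2ko line 3, and -0.61 without Hdac2ko line 1. The 6 were Cd74, the MHC class II genes H2-Aa, H2-Ab1, H2-Eb1 and H2-DMa, and the protease gene Ctss. Of these, H2-Ab1, at -4.93, had adjusted p up to 0.0525 without 1 line. The immune and endothelial list had the median of -2.37 across the same lines, and the fibroblast list that of -2.42.

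Few members of the lists of signalling and apoptosis genes passed the threshold. Of 41 TGF-beta genes, 3 fell, and 10 fell and 1 rose when adjusted over the list alone, with a median of -0.18 that turned to 0.00040 with each array centred on its median and to 0.0081 without Hdac2ko line 1 (camera adjusted p = 1.78e-05, adjusted p = 0.484 with an estimated correlation). It was -0.34 without Hdac2wt line 1, -0.087 without Hdac2wt line 2 and -0.45 without Hdac2ko line 3. The 3 were the secreted matrix protein gene Tgfbi at -4.22, the endothelial co-receptor gene Eng at -4.08 and the integrin gene Itgb6 at -3.23, and Itgb6 lost its call without 1 line in 5 cases (adjusted p up to 0.137). The call of Itgb6 also ended with repeated quantile normalization, no trend, robust estimation and array weights (adjusted p from 0.0509 to 0.0555). The receptor genes Tgfbr1 and Tgfbr2 differed by -0.89 (SE 0.23, adjusted p = 0.144) and -0.60 (SE 0.29, adjusted p = 0.387), and Smad4 by -0.04 (SE 0.20, adjusted p = 0.926), a sign that turned to 0.13 with centring. Of 37 WNT, Notch and Hedgehog genes, 2 fell, and 6 when adjusted over the list alone, with a median of -0.63 (camera adjusted p = 1.28e-08, adjusted p = 0.161 with an estimated correlation). They were Dkk3 at -3.14 and the Notch target gene Heyl at -0.92, and Heyl lost its call in each of the 6 fits without 1 line (adjusted p from 0.0686 to 0.131), with centring (adjusted p = 0.0794), with repeated quantile normalization (adjusted p = 0.0602) and with robust estimation (adjusted p = 0.0519). Of 34 inflammatory genes, the cytokine gene Il1b fell by 2.74, and 3 fell and 1 rose when adjusted over the list alone. That list had a median of -0.17 (camera adjusted p = 0.0394, adjusted p = 0.484 with an estimated correlation), which turned to 0.0064 with centring, and its call ended without Hdac2wt line 2 (median 0.065, adjusted p = 0.0618), Hdac2wt line 3 (adjusted p = 0.104) and Hdac2ko line 1 (median 0.15, adjusted p = 0.399). Its median was -0.26 without Hdac2wt line 1 and -0.058 without Hdac2ko line 3. Over all alternatives with camera its adjusted p ran from 0.00167 to 0.399. Of 35 apoptosis regulators 0 passed over all genes or adjusted over the list alone (limma, 5 lower and 1 higher at an unadjusted p under 0.05), with Casp6 at -0.98 (adjusted p = 0.128) and Bok at -1.55 (adjusted p = 0.132), which passed without Hdac2ko line 1 at -1.96 (adjusted p = 0.0359, up to 0.317 over the alternatives with genotype as the sole term). The median of these regulators was -0.03, turning to 0.15 with centring (camera adjusted p = 0.0150, adjusted p = 0.161 with an estimated correlation), and the call ended without Hdac2ko line 1 (median 0.058, adjusted p = 0.0932, the highest over the alternatives, against 0.00569 as the lowest). The median was -0.010 without Hdac2wt line 2, -0.078 without Hdac2wt line 3, 0.039 without Hdac2ko line 2 and -0.21 without Hdac2ko line 3. For comparison, the median of the immune and endothelial markers over these lines was -2.37, and whether these lists followed it line by line was not tested.

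Epithelial genes were lower as a list without any single gene past the threshold. Of 39 measured epithelial junction and identity genes 0 passed over all genes or adjusted over the list alone (limma), 3 were lower at an unadjusted p under 0.05, the median was -0.79, and camera gave adjusted p = 1.16e-07 (adjusted p = 0.484 with an estimated correlation). Without Hdac2ko line 3 that median was -0.047 (adjusted p = 0.00688), and without Hdac2ko line 1 it was -1.30 (adjusted p = 1.26e-11, the lowest over the alternatives). Cldn4, a tight junction gene, differed by -2.23 (SE 0.57, adjusted p = 0.144) and the transcription factor gene Grhl2 by -1.82 (SE 0.55, adjusted p = 0.210), though without Hdac2wt line 2 Grhl2 passed at -2.50 (adjusted p = 0.00429, up to 0.463 over the alternatives with genotype as the sole term). The mean of the list was 7.98 in Hdac2ko line 3 and from 9.61 to 10.45 in the other lines. Of 35 genes of the classical subtype and the endoderm, Lyz2, Vsig2, Gkn1 and Kcne3 fell, by 6.72, 3.52, 2.06 and 3.20, and the count was 4 when adjusted over the list alone. Kcne3 lost its call without 1 line in 5 cases, with adjusted p up to 0.169, and also without a trend (adjusted p = 0.0535) or with array weights (adjusted p = 0.0622). The median was -0.57 (camera adjusted p = 5.88e-05, adjusted p = 0.484 with an estimated correlation), and without Hdac2ko line 3 it was 0.042 and the call was lost (adjusted p = 0.187, against 6.31e-08 as the lowest over the alternatives). It was -1.01 without Hdac2wt line 3, -1.25 without Hdac2ko line 1 and -0.87 without Hdac2ko line 2. Of 29 acinar and endocrine genes 0 passed over all genes or adjusted over the list alone (limma, 1 lower at an unadjusted p under 0.05), with a median of -1.14 (camera adjusted p = 1.87e-05, adjusted p = 0.533 with an estimated correlation). The mean of that list was 10.04 in Hdac2wt line 3 against at most 7.09 elsewhere, and the elastase gene Cela1 read 12.70 there. Without Hdac2wt line 3 the median was -0.031 and the call was lost (adjusted p = 0.0743, against 2.12e-08 as the lowest over the alternatives). The lists of immune and endothelial and of fibroblast markers had medians of -2.37 and -2.42 over these lines.

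Growth-related lists were the ones called higher in the lines labelled Hdac2ko, in small steps spread over many members. All 41 DNA replication genes had positive differences, with a median of 0.63 against 0.12 for all genes (camera adjusted p = 4.91e-06, adjusted p = 0.533 with an estimated correlation). The helicase gene Mcm7 was at 0.63 (adjusted p = 0.133) and the origin recognition gene Orc6 at 0.83 (adjusted p = 0.133). All 32 MYC target and ribosome biogenesis genes were positive, with a median of 0.46 (camera adjusted p = 3.41e-05, adjusted p = 0.484 with an estimated correlation), among them Nop2 at 0.80 (adjusted p = 0.0919) and Mybbp1a at 0.54 (adjusted p = 0.154). Of 35 mitotic genes, 33 were positive, with a median of 0.49 (camera adjusted p = 0.0105, adjusted p = 0.673 with an estimated correlation), Prc1 at 1.14 (adjusted p = 0.251) and Ttk at 1.12 (adjusted p = 0.255). The mitotic list mean was 8.91, 9.36 and 9.69 in the lines labelled Hdac2wt. It was 9.84, 9.24 and 10.41 in the lines labelled Hdac2ko, so the genotypes overlapped. For DNA replication the highest mean in lines labelled Hdac2wt was 9.37 and the lowest in lines labelled Hdac2ko was 9.41. For MYC targets these were 10.49 and 10.56. The mitotic median was 0.33 without Hdac2wt line 1, 0.82 without Hdac2ko line 2 and 0.30 without Hdac2ko line 3. The mitotic call ended without Hdac2wt line 1 (adjusted p = 0.210) or Hdac2ko line 3 (adjusted p = 0.382) and with centring (adjusted p = 0.142), and its lowest adjusted p over the alternatives was 1.10e-06. In these 3 lists 0 genes passed over all genes and 0 when adjusted over the list alone (limma), while 17, 10 and 4 were higher at an unadjusted p under 0.05. Myc itself differed by 0.43 (SE 0.24, adjusted p = 0.421). Across the same lines the immune and endothelial markers had their median at -2.37, and the mean of that list was from 9.15 to 9.76 in lines labelled Hdac2wt and from 6.60 to 6.89 in lines labelled Hdac2ko.

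The lists left did not pass camera, and calls that some of them gained under alternatives are given with the other alternatives. Chac1 was the sole member of 30 stress response genes that rose over all genes, against 5 when adjusted over the list alone, and the median was 0.34 (camera adjusted p = 0.0880), with 0.16 without Hdac2wt line 1 and 0.63 without Hdac2ko line 3. Slc2a3, a glucose transporter gene, was the sole member of 33 hypoxia and glycolysis genes that fell, by 1.86 (limma adjusted p = 0.0442), against 2 when adjusted over the list alone. Its call ended without 1 line in 5 cases (adjusted p up to 0.140), with centring (adjusted p = 0.0627), with repeated quantile normalization (adjusted p = 0.0729) and without a trend (adjusted p = 0.0535). The hypoxia list had a median of 0.03 and a mean of -0.10, with camera pointing down (adjusted p = 0.105). The list of 31 p53 targets and cell cycle inhibitors had a median of 0.06, a mean of -0.01 and a downward camera direction (adjusted p = 0.253), with 0 members past over all genes (limma, 2 higher and 3 lower at an unadjusted p under 0.05) and 1 lower when adjusted over the list alone. Its members Eda2r and Cdkn2a differed by -1.20 (adjusted p = 0.0626) and 0.72 (adjusted p = 0.186). Eda2r passed without Hdac2wt line 2 at -1.41 (adjusted p = 0.0301, up to 0.212 over the alternatives with genotype as the sole term) and with the filter at the 25th percentile of signal (adjusted p = 0.0482). For the neighbouring inhibitor gene Cdkn2b the difference was 0.54 (adjusted p = 0.403). The 28 basal and squamous genes had a median of 0.05, a mean of -0.12 and a downward camera direction (adjusted p = 0.331), with Dsg3 at -0.54 and Ly6d at -1.44 (adjusted p = 0.264 and 0.320). Ly6d passed without Hdac2wt line 2 at -2.14 (adjusted p = 0.00950, up to 0.573 over the alternatives with genotype as the sole term). KRAS and ERK output genes had a median of 0.43 over 29 members (camera adjusted p = 0.274), with Fos at -1.32 (adjusted p = 0.178) and Epha2 at 0.49 (adjusted p = 0.181). Cholesterol and fatty acid synthesis genes had a median of 0.33 over 27 members, all positive (camera adjusted p = 0.0666), with Fasn at 0.34 and Scd1 at 0.94 (adjusted p = 0.307 and 0.323). Neuronal genes under REST had a median of 0.19 over 38 members (camera adjusted p = 0.0790), with Bdnf at 0.96 and Rims2 at 1.12 (adjusted p = 0.0950 and 0.122). Interferon response genes had a median of -0.07 over 33 members (camera adjusted p = 0.136), with Gbp5 at -0.58 and Irgm1 at 1.22 (adjusted p = 0.129 and 0.194), and Gbp5 passed with cyclic loess at -0.68 (adjusted p = 0.0360, up to 0.329 over the alternatives with genotype as the sole term). With cyclic loess the medians of the hypoxia, p53 and basal lists turned to -0.076, -0.11 and -0.044, and with centring that of the interferon list turned to 0.10. Without 1 line the interferon median was 0.17 (Hdac2wt line 2), 0.23 (Hdac2ko line 1 or 2), -0.33 (Hdac2wt line 1) and -0.30 (Hdac2ko line 3). The p53 median ran from -0.076 without Hdac2ko line 2 to 0.15 without Hdac2wt line 2, the basal median from -0.041 without Hdac2ko line 1 to 0.13 without Hdac2wt line 3, and the hypoxia median from -0.27 without Hdac2wt line 1 to 0.32 without Hdac2wt line 2. The KRAS median was 0.12 without Hdac2ko line 3, and the cholesterol median was 0.027 without Hdac2ko line 1. In the basal, KRAS, cholesterol, neuronal and interferon lists 0 members passed over all genes or adjusted over the list alone (limma), with at most 4 higher and 2 lower in a list at an unadjusted p under 0.05.

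In all, 16 of 26 lists passed camera, 13 down and 3 up, 0 passed with an estimated correlation, and fry, which asks whether the members move one way on balance, called 5. Fry called 15 lists for changes in either direction.

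The female-specific transcript Xist and the Y-linked genes split the lines across the genotypes. Xist read from 12.39 to 13.13 in Hdac2wt lines 1 and 2 and Hdac2ko lines 1 and 2, and 5.45 and 5.19 in Hdac2wt line 3 and Hdac2ko line 3. The Y-linked gene Uty read 9.72 and 9.41 in those last lines and from 4.42 to 4.68 in the others. Between the genotypes the differences were -0.44 for Xist, -0.07 for Uty, -0.07 for Eif2s3y and 0.01 for Kdm5d, with limma adjusted p from 0.944 to 0.997. The list had a median of -0.07 over 4 members (camera adjusted p = 0.513).

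Correlations between lines were higher on average within a genotype than between the genotypes, with overlap. Pearson correlations across genes, which are not independent replicates, averaged 0.959 within and 0.928 between the genotypes, a difference of 0.0301 (exact permutation over 10 splits, p = 0.1, the smallest possible). The highest correlation between the genotypes, 0.949 for Hdac2wt line 2 with Hdac2ko line 1, lay above the lowest within a genotype, 0.936 for Hdac2ko line 1 with Hdac2ko line 3. The first principal component of the 2000 most variable genes held 51.3% of their variance and the next 23.8%.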

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

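The tests in this part were chosen after the comparison of the genotypes was seen. The predictions for cells of other types were written before the values of the held-out markers were seen, and the remaining predictions after.

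Among 13767 probe sets with no listed gene or with several genes, which no comparison above uses, 11 were lower in the lines labelled Hdac2ko and 0 were higher (limma, adjusted over these probe sets). Of the 11, 8 had no listed gene and 3 had several, and 1615 probe sets had an unadjusted p under 0.05. They drew attention as a signal outside the genes that were tested.

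Immune and endothelial markers were lower in the lines labelled Hdac2ko. The highest median of the list under 3 other scalings was -2.19, so the choice among these scalings did not account for the shift. They start from values already normalized with RMA and put the median of all genes between 0.00088 and 0.29. They therefore do not test the original normalization. Cells of other types in the samples labelled Hdac2wt are a candidate explanation, with macrophage Lyz2 at 12.73 there and 6.01 in lines labelled Hdac2ko, and the labels name no sorting step. Held-out macrophage and endothelial markers, with 34 of 35 lower, had a median of -1.73 (quartiles -3.44 and -1.27), none of them belongs to another list, and 5 lay above the median gene in the lines labelled Hdac2ko. For a change of the carcinoma cells alone, the list means had to be apart. The lowest in samples labelled Hdac2wt exceeded the highest in lines labelled Hdac2ko by 2.26. The held-out markers also had to stay in place, and their median was -1.73. That requirement was set after the values were seen, so it decides nothing about the carcinoma cells. The prediction for cells of other types, written before the held-out values were seen, was met. Red cell and exocrine transcripts, given further below, also stood out in some samples labelled Hdac2wt. These values go with other cells in those samples as a source of the markers, though T and NK cell markers did not move. How much of a gene's difference comes from genotype and how much from cell content cannot be told apart in these 6 samples.

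Mesenchymal genes and the PDGF receptors were lower as well. Held-out fibroblast markers, 19 of 20 lower, had a median of -1.92, which fibroblasts in the samples labelled Hdac2wt would give and which a mesenchymal state of the carcinoma cells would give too. Adjusting for the immune and endothelial mean does not separate these, because that mean correlated with genotype at -0.988 and the median standard error grew by a factor of 6.94. The 2 explanations cannot be told apart here for these genes.

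Hdac2 was not lower in the lines labelled Hdac2ko. A probe set that also reads exons outside the deleted part may account for the difference of 0.21, and probes inside that part were not measured apart. Exchanged labels would need a signal lower in the samples labelled Hdac2wt, and the interval began at -0.45, so that neither explanation can be told apart from the other with 1 value per gene.

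The labelled genotypes gave 418 genes, 1 of 10 splits of the 6 lines into 3 and 3, and the highest number in the other splits was 0. So few splits cannot give a share under 0.05. The other splits mix the genotypes, which puts the differences between them into the residual spread. Their 0 is therefore not the count to be had without any effect.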

How the results depend on the processing

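The covariate and the omission of other-cell genes were chosen after the data were seen, and the other alternatives before. Over the alternatives that were set before the data were seen and use all 6 lines, 764 values of named genes kept their direction and their side of the threshold, 26 lost the call, 2 gained it and 6 changed sign. For lists tested with camera at the preset correlation under the same alternatives, 240 kept both, 7 lost the call, 9 gained it and 1 changed direction. With an estimated correlation 16 lists lost the call and 10 kept both, and with fry 11 lost it, 13 kept both and 2 changed direction. Without 1 line, 427 gene values kept both, 103 lost the call, 4 gained it and 18 changed sign. Pdgfrb kept its call in all of these, with adjusted p from 0.000398 to 0.0122, and Egfr did not reach the threshold of 0.05 in any, with adjusted p from 0.0532 to 0.234. Hdac2 ran from 0.04 to 0.45. No paired analysis was possible because the labels give no shared replicate numbers. Signal over background was not known for any array, which limits statements on dim genes.

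The filter at the median signal gave 182 genes, 163 lower and 19 higher, in a test of fewer genes. It also gave a difference between mean correlations of 0.117, which was 0.0671 with the filter at the 25th percentile, and an interferon list median of 0.21. List medians under that filter, over fewer members, were -3.95 for immune and endothelial, -2.73 for acinar, -0.44 for receptor tyrosine kinase, -0.94 for classical, -0.30 for inflammatory, -0.13 for antigen presentation, -0.30 for basal and -0.065 for p53 genes. Centring gave 103 higher genes and positive values for Eif2s3y (0.11), Hdac3 (0.17), Smad4 (0.13) and Uty (0.11). Cyclic loess gave 16 higher genes, with Kdm5d at -0.090, and array weights put Kdm5d at -0.048. Without a trend 52 genes were higher. Pdgfra lost its call at -3.37 with repeated quantile normalization, -3.40 without a trend and -3.32 with array weights, and its adjusted p without 1 line ran from 0.0141 to 0.164. A threshold of 0.1 gave 674 genes, 125 of them higher. Camera with an estimated correlation called 0 lists, and fry called 5, with 15 in its mixed test. The direction of fry was upward for basal and squamous genes (median 0.053) and for p53 targets (median 0.057). Except for the filter, the cause was not tested.

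Without 1 line the count ran from 192 to 385, lower genes from 190 to 377 and higher genes from 2 to 36. The lines that moved the count by the most are given beside it above, and fewer samples were tested. Pdgfra ran from -3.98 to -2.93, Xist from -2.94 to 1.96, Eif2s3y from -1.61 to 1.75, Uty from -1.68 to 1.66, Kdm5d from -0.88 to 1.10, Hdac3 from -0.18 to 0.10 and Smad4 from -0.24 to 0.074. List medians ran from 0.12 to 0.51 for KRAS output, from -0.27 to 0.32 for hypoxia, from 0.027 to 0.50 for cholesterol synthesis and from -1.24 to 1.38 for Y-linked genes with Xist. The direction of camera turned for KRAS output without Hdac2ko line 3, hypoxia without Hdac2wt line 2, cholesterol synthesis without Hdac2ko line 1 and Y-linked genes with Xist without Hdac2wt line 3.

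Lists without a call gained one in some cases (camera adjusted p, with the range over the alternatives). Without Hdac2wt line 1 these were HDAC complexes (0.0261), basal genes (0.0192, from 0.0192 to 0.978) and hypoxia (4.04e-06), and without Hdac2wt line 3 cholesterol (0.0315), stress response (0.0185) and neuronal genes (0.0161). Without Hdac2ko line 1 it was KRAS output (0.0172, from 0.0172 to 0.546), and without Hdac2ko line 2 cholesterol (0.0140) and neuronal genes (0.0182). Without Hdac2ko line 3 they were cholesterol (0.00191, from 0.00191 to 0.665), hypoxia (0.0174, from 4.04e-06 to 0.859), interferon (0.000419, from 0.000419 to 0.995) and stress response (0.000217, from 0.000217 to 0.593). Cyclic loess called cholesterol, neuronal and stress response genes. Centring called hypoxia and interferon, both downward, with medians of 0.21 and 0.10 where the median of all genes was 0.29. Quantile normalization called neuronal genes (0.0150, from 0.0150 to 0.995), array weights called hypoxia, and the filter at the 25th percentile called cholesterol and stress response. The apoptosis call ended with the filters (0.0555 and 0.0642), and the inflammatory call with the filters (0.156 and 0.109), quantile normalization (0.0617) and cyclic loess (0.280).

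With the immune and endothelial mean as a covariate, 0 genes were called, 0 lower and 0 higher (limma). Of 19938 genes, 733 had an unadjusted p under 0.05, a smaller share than the 0.05 to be had without any effect. The immune and endothelial mean was nearly collinear with genotype, so standard errors grew by a factor of 6.94 and no gene's estimate can be interpreted by itself. Of the named genes 25 changed sign, 45 lost the call and 22 kept both. Pdgfrb was at -4.05 without a call. The estimates that changed sign were negative for Hdac2 (-2.0), Smarca1 (-2.27), Steap1 (-0.56), Epha2 (-0.14), Cdkn2b (-2.38), Hdac8 (-0.57) and Myc (-1.43). They were positive for Pdgfra (2.53), H2-Aa (0.035), H2-Ab1 (1.26), Cldn4 (1.92), Grhl2 (4.16), Fos (2.06), Dsg3 (0.27), Ly6d (4.28), Eda2r (1.58), Gbp5 (0.71), Mmp9 (0.34), Cela1 (13.11), Chga (3.43), Dpt (4.21), Heyl (0.033), Tgfbr2 (1.22), Eif2s3y (20.45) and Uty (18.76). Leaving out the genes of other-cell lists gave 330 genes, 301 lower and 29 higher, and lists without shared members gave 16 calls, all lost with an estimated correlation (adjusted p of 0.104 or more). These omissions drop listed markers alone. Genes of those cells that are on no list stay in, so the remaining calls do not show a difference free of cell content.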

Other observations

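The lists of other cell types described here were written after the comparison of the genotypes was seen and before their values were looked at. The genes of this paragraph were picked after their values were seen, and Cpa1 and Prss2 belong to the acinar and endocrine list fixed earlier. Red cell transcripts stood out in 2 of the samples labelled Hdac2wt, and exocrine transcripts in 1. The haem synthesis gene Alas2 read 10.57 and 11.23 in Hdac2wt lines 2 and 3 and from 6.79 to 7.27 in the other 4 lines, and the red cell anion exchanger gene Slc4a1 read 9.58 and 9.24 against 6.85 to 7.14. These 2 genes were the measured members of the erythroid list, with a median of -2.20. The digestive enzyme genes Cpa1 and Prss2 read 13.64 and 13.55 in Hdac2wt line 3 and at most 9.50 and 9.11 elsewhere. From the list of B and plasma cells, of which 1 of 10 genes passed the threshold, the antibody joining chain gene Jchain read 10.76 in Hdac2wt line 3 and at most 6.88 elsewhere.

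Held-out macrophage and dendritic cell markers had a median of -3.21, with 12 of 17 past the threshold and lower, among them Trem2 at -1.73 and Cd163 at -1.86. Held-out endothelial markers had a median of -1.40, with 7 of 18 lower, among them Erg at -1.53 and Robo4 at -1.93, and held-out fibroblast markers had 6 of 20 lower. These genes are given as examples picked after their values were seen. T and NK cell markers had a median of 0.01 over 10 genes with 0 past the threshold. Medians were -0.28 for B and plasma cells (1 of 10 lower), -0.47 for mast cells, 0.13 for Schwann cells, -0.92 for pericytes and vascular smooth muscle (1 of 9 lower), -0.12 for adipocytes and -0.06 for mesothelial cells. In the lines labelled Hdac2ko, 1 of 17 macrophage, 4 of 18 endothelial and 5 of 20 fibroblast held-out markers lay above the median gene.

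Hdac2ko line 3 differed from the other lines in epithelial genes. Cdh1 read 9.94 there and from 12.18 to 12.58 in the other 5 lines, and Epcam read 5.65 there against 9.42 or more.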
